A study of Homo sapiens with 8 samples.

How the data were processed

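RNA of the human breast cancer cell line MDA-MB-231, an established triple-negative line, was measured on 8 single-colour Agilent 8x60K gene expression microarrays, 2 arrays in each of 4 groups. Per the labels' protocols, cells were kept in a serum-containing medium, and all groups were taken at 24 h. Attached cells stayed on tissue-culture plastic with DMSO or with a treatment that the labels call A76, which they do not spell out. Suspension cells were trypsinised and held over agar, and were stable either for a control construct, Scr, or for a short hairpin RNA (shRNA) against AMPK alpha 2, the catalytic subunit encoded by PRKAA2. Descriptions of the attached arrays also carry the tag scr, so these cells may hold the control construct too. Total RNA was column-purified with DNase treatment, and Cy3-labelled cRNA was made from oligo-dT primed cDNA, per the labels' protocols.

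Each array came as Agilent Feature Extraction output, version 11.5.1.1 per the file headers. Its spot intensity values are given on a linear scale as deposited: the mean and background intensities of each spot, and a processed signal that the software had already corrected for background, per the file headers. The deposited value table holds log2 values by the authors. Set against the scanner values of the same array, 99.2% to 99.6% of its values equalled log2 processed signal plus 1 constant per array within 0.001. That constant differed from minus the array's 75th percentile by 0.003 to 0.007, so its scale and centring were recovered, and it holds no ratio and hence no direction. Medians of the 8 columns ran from -4.13 to -3.83. That table served only as an alternative.

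For the main values, log2 of the processed signal was taken and each array's 75th percentile over the non-control spots was subtracted. Control spots and spots marked as outliers by the software (246 to 563 per array) were left out, and spots of the same probe were averaged. Probe accessions were matched without version to a RefSeq gene table of assembly GRCh38.p14, used for names only. Of 50599 non-control probes, 28170 were named this way, 4386 of them differently from the array files, and 22429 kept the file's name. Coordinates are those in the array files, which use hg19. A probe was tested if it was well above background on both arrays of at least 1 group, which kept 29845 probes (59.0%). Each gene was read by its tested probe with the highest mean over the 8 arrays, giving 22390 genes, of which 5376 had several tested probes. Among called genes with several probes, all probes had the same sign for 62 of 67 in the A76 comparison, 14 of 15 in the shRNA comparison and 1999 of 2374 in the suspension comparison. A probe was called the other way in 1, 0 and 61 of them.

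Between 53.9% and 60.4% of probes per array were well above background, and no spot was saturated. The 75th percentile of the signal was 317 and 280 units on the DMSO arrays, 250 and 239 on the A76 arrays, 285 and 248 on the Scr arrays and 312 and 292 on the shRNA arrays. The number of arrays limits the precision. The median standard error of a log2 difference was 0.15. All 8 arrays lay on 1 slide and were read in 1 scan. Attached groups filled 1 of its rows and suspension groups the other, while control groups and the groups given A76 or the shRNA alternated by column, so slide position and group cannot be told apart. The labels do not say whether the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

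Groups were compared with limma 3.58.1 in R 4.3.3: 1 fit over the 4 groups with 4 residual degrees of freedom, lmFit and eBayes (prior degrees of freedom 2.32), and Benjamini-Hochberg adjustment over the genes tested in each comparison. Genes with adjusted p under 0.05 were called. Folds of genes not well above background on either array of a group are bounds: the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal well above background and the probe's own value. Tested genes read on none of a comparison's 4 arrays numbered 295 (A76), 461 (shRNA) and 105 (suspension), with median log2 changes of 0.44, -0.13 and 0.66. Of these genes, 2 were called lower with A76, 1 higher with the shRNA, and 23 higher and 2 lower in suspension.

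Before the data were examined, the groups, tests, alternatives, 35 gene lists and the rule for naming genes were fixed. Named per comparison were all AMPK subunits; the 8 largest rises and 8 largest falls among called, annotated genes read on all 4 arrays with no overlap between groups; at most 3 bounds per direction; up to 4 members, by smallest p, of the 8 lists with the smallest set-test p; and genes called both with A76 and with the shRNA. MMP3 was added after the values were seen, to complete its list. Lists with at least 5 tested members (34 of 35) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 102 tests. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, camera refers its statistic to the 4 residual degrees of freedom of the fit, which raises p for any list. Marker lists of luminal breast cells, keratinocytes, fibroblasts and blood cells stood for other cells a culture could hold.

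The pipeline was tested on simulated data with the real genes' spread, 22386 genes per comparison. Changes of 1 log2 unit were recovered for 61.2% of genes in the A76 comparison, 64.2% in the shRNA comparison and 70.1% in the suspension comparison. Changes of 2 log2 units were recovered for 89.4%, 93.9% and 87.9%, and changes of 0.5 for 1.49%, 0% and 1.49%. There were 12, 7 and 10 false calls. Only 67, 67 and 66 genes were changed by 0.5, 1 and 2, whereas 39.1% of tested genes were called in the real suspension comparison. The adjustment is looser where more genes change, so these rates do not carry over to suspension. The smallest log2 change called there was 0.27. A simulated list of 25 genes shifted by 0.3 had a camera p of 3.03e-09, 4.78e-14 and 2.61e-14 at the preset correlation, and 0.00272, 0.00110 and 0.00106 with an estimated one. Of 50 unshifted lists, 3, 2 and 1 had a camera p under 0.05. Simulated genes were drawn independently, so these values do not test camera on correlated genes. Estimated correlations in the real lists ran from -0.06 (AMPK subunits) to 0.63 (G2/M and mitosis), against the preset 0.01. Chance values from shared control arrays were taken from 200 simulated draws.

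Alternatives covered array scaling (median, quantile), normexp background correction with an offset of 50, the deposited value table, the filter on dim probes, the probe rule, the fit (2 groups only, replicate block, intensity trend with and without robust eBayes), the threshold, and each array left out in turn. Array numbers in the labels did not settle a pairing, so the fit had no block. Slide and scan could not be blocked, with 1 of each. No genome sequence was used here.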

Results

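Transcripts of MDA-MB-231 breast cancer cells were profiled on 8 arrays, 2 for each of 4 conditions at 24 h. These were attached cells with the vehicle DMSO, attached cells with A76, suspension cells carrying the Scr control construct, and suspension cells carrying an shRNA against AMPK alpha 2. AMPK is a kinase that responds to a low energy state of the cell. Within a group the 2 arrays correlated across genes with r = 0.996 (DMSO), 0.994 (A76), 0.993 (Scr) and 0.993 (shRNA). Between groups r was nearly as high, 0.992 to 0.993 for DMSO with A76 and 0.990 to 0.992 for Scr with the shRNA. The median absolute log2 difference was 0.16 between Scr array 1 and shRNA array 1. It was 0.21 between Scr array 2 and shRNA array 1, and 0.19 between shRNA array 2 and either Scr array. Within groups it was 0.18 between the Scr arrays and 0.16 between the shRNA arrays. The leading principal component held 68.0% of the variance and separated attached from suspension arrays, while the next pair held 8.29% and 7.71%. A76 against DMSO, the shRNA against Scr, and suspension against attachment were compared, each with 2 arrays against 2 and 22390 genes.

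PRKAA2, the gene the shRNA targets, was read by 1 probe on chromosome 1 (57180117 to 57180176, hg19). Its log2 signal relative to the array's 75th percentile was 0.46 and 0.22 on the Scr arrays and -0.15 and 0.00 on the shRNA arrays. Both shRNA arrays thus lay below both Scr arrays. In either direction, 38.3% of all tested genes had no overlap between these groups, against 33.3% by chance for 2 arrays against 2. The log2 change of -0.41 ± 0.14 (SE) had an unadjusted limma p of 0.0269 and an adjusted p of 0.361 over all genes, and did not pass the threshold. Under the other settings it lay between -0.53 and -0.30, with an adjusted p from 0.206 to 0.662. In attached cells PRKAA2 averaged 0.29 ± 0.11 (SD, n = 2) with DMSO and 0.20 ± 0.18 with A76, and in suspension 0.34 ± 0.17 with Scr. Of the 7 AMPK subunit genes, PRKAG2, a regulatory gamma subunit (chromosome 7, 151254197 to 151254256), fell 2.35-fold in suspension, by 1.24 ± 0.10 on the log2 scale (limma adjusted p = 0.000542). By the probe used for each gene, no other subunit passed in any comparison. PRKAA1, the other catalytic subunit, had log2 changes of 0.09 with A76, 0.17 with the shRNA and 0.13 in suspension by its brighter probe. Its dimmer probe read -0.52 in suspension, with an unadjusted limma p of 0.00747 in a fit of all probes. The largest other change, -1.18 ± 0.70 for PRKAG1 with A76, had a large error. As a list, the subunits had a median log2 change of 0.09 but a mean of -0.07 with A76 (camera adjusted p = 0.673), a median of -0.17 with the shRNA (adjusted p = 0.477) and of -0.11 in suspension (adjusted p = 0.572). The plot of 8 genes by array shows PRKAA2 and PRKAG2 beside genes from each comparison.

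**Figure D1:**
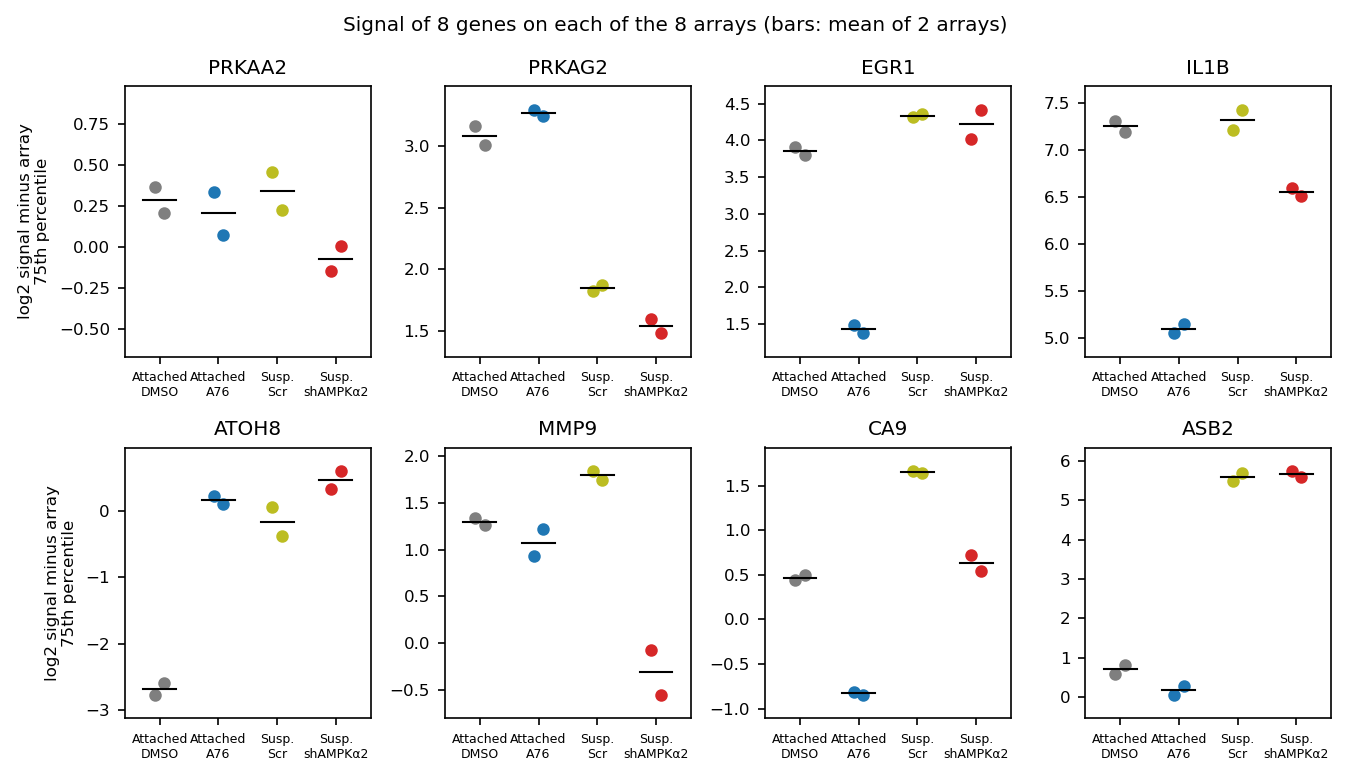
Log2 signal minus the array's 75th percentile (vertical axis) of 8 genes in the 4 groups (horizontal axis), with a point for each array and a bar at the mean of the 2 arrays. EGR1 and IL1B lie lower with A76 than with DMSO, MMP9 lies lower with the shRNA than with Scr, CA9 is lower in both of these comparisons, and ASB2 is higher in all 4 suspension arrays than in the 4 attached arrays; PRKAA2 differs between Scr and the shRNA by -0.41, which did not pass the threshold.

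In attached cells given A76, some transcripts of growth-factor-induced regulators, inflammatory cytokines and matrix proteases were lower than with DMSO: 10 of 24, 8 of 23 and 5 of 15 in the lists tested, with none higher. These list shifts passed by camera at the preset correlation but not with an estimated correlation (adjusted p = 0.0968, 0.146 and 0.146). EGR1, an immediate early transcription factor, fell by 2.42 ± 0.15 on the log2 scale, from 3.85 ± 0.08 to 1.43 ± 0.08 (SD, n = 2; limma adjusted p = 0.00357). IL1B, an inflammatory cytokine, fell 4.43-fold from a high level, from 7.25 ± 0.09 to 5.10 ± 0.07. SERPIND1, a thrombin inhibitor, had the largest fall, 19.4-fold. ATOH8, a basic helix-loop-helix transcription factor, rose 7.18-fold and CEMIP, a hyaluronan-binding protein, 6.86-fold. Altogether 118 genes were higher and 173 lower at a limma adjusted p under 0.05, 1.30% of those tested, and 61 and 102 of them changed at least 2-fold.

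Further rises with A76 were those of TGFB2, a growth factor (1.92 ± 0.10, 3.78-fold), SPINK4 (3.68-fold), EDN2, an endothelin (3.61-fold), NFE2 (3.34-fold), and NEURL3 and WFDC21P (both 3.24-fold). Limma adjusted p for the 8 largest rises lay between 0.00273 and 0.0304. The other large falls were those of TNFSF15, a cytokine of the tumour necrosis factor family (5.81-fold), SLCO4A1, an organic anion transporter (5.35-fold), MMP10, a stromelysin (5.16-fold), PLA2G4D, a cytosolic phospholipase (4.69-fold), and EGR2 (4.29-fold), with limma adjusted p from 0.00273 to 0.0344 for the 8. CCN5, RTP3 and PCAT18 were not well above background with DMSO and rose at least 6.06-fold, at least 4.25-fold and at least 2.94-fold. SLITRK6, DHRS9 and CYP3A5 were not well above background with A76 and fell at least 3.82-fold, at least 2.71-fold and at least 2.60-fold.

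The ERK feedback and immediate early genes moved furthest as a list with A76. Of 24 members, 10 fell and 14 did not pass, and 19 fell when adjusted over the list alone. Beside EGR1 and EGR2, SPRY4, an inhibitor of receptor tyrosine kinase signalling, fell 2.85-fold and EREG, an EGF-family ligand, 2.80-fold. Their median log2 change was -0.73, with a camera adjusted p of 3.14e-22, but adjusted p = 0.0968 with an estimated correlation. Among matrix proteases and inhibitors, 5 of 15 fell (8 adjusted over the list alone): MMP10, the collagenase MMP1 (2.01-fold), tissue plasminogen activator PLAT (2.05-fold), the urokinase receptor PLAUR (1.90-fold) and the stromelysin MMP3 (3.33-fold); the list's camera adjusted p was 1.44e-09, and adjusted p = 0.146 with an estimated correlation. In the NF-kB and cytokine list 8 of 23 fell and none rose, against 10 lower and 3 higher when adjusted over the list alone. Members that fell included the prostaglandin synthase PTGS2 (3.69-fold), the colony-stimulating factor CSF3 (3.36-fold) and IL1A (2.45-fold), and the list's camera adjusted p was 1.64e-06, with adjusted p = 0.146 with an estimated correlation.

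Hypoxia response genes had a median log2 change of -0.34 with A76. Of 19 members, 3 fell (6 adjusted over the list alone), namely the carbonic anhydrase CA9 (2.46-fold), the angiogenic factor VEGFA (2.14-fold) and NDRG1 (2.53-fold), while ANGPTL4 read -1.01 and did not pass. The camera adjusted p was 4.39e-07, and adjusted p = 0.277 with an estimated correlation. No glycolysis gene of 21 passed over all genes and 1 was lower adjusted over the list alone. PFKFB4 read -0.65, ENO2 -0.34, SLC2A3 -0.64 and PKM -0.25, and the list's median of -0.19 had a camera adjusted p of 0.000255, with adjusted p = 0.253 with an estimated correlation. Of 20 SRF and actin cytoskeleton genes, FILIP1L rose 2.58-fold and 4 were higher adjusted over the list alone. TPM1, TAGLN and MYL9, which encode contractile proteins, read 0.55, 0.83 and 0.63 without passing, and the camera adjusted p was 0.000265, with adjusted p = 0.253 with an estimated correlation.

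Weaker camera results with A76 were seen in 6 more lists. Of 17 breast stem and progenitor markers the Notch ligand JAG1 fell 2.80-fold and 6 were lower adjusted over the list alone, while SOX9 (-0.66), ITGA6 (-0.54) and HES1, which was not well above background with A76, did not pass; the camera adjusted p was 0.00516, with adjusted p = 0.277 with an estimated correlation. All 26 G2/M and mitosis genes had positive values, among them HMMR at 0.31 and CCNB2 at 0.30, but none passed over all genes or adjusted over the list alone; the median of 0.18 had a camera adjusted p of 0.00851, and adjusted p = 0.687 with an estimated correlation. YAP/TAZ targets went both ways, with 3 of 23 higher and 1 lower, a median of 0.20, a camera adjusted p of 0.0102 and adjusted p = 0.277 with an estimated correlation. ER chaperones, ribosomal proteins and integrins had medians of -0.10, 0.11 and -0.08 with camera adjusted p of 0.015, 0.0173 and 0.0347, and adjusted p = 0.453, 0.489 and 0.463 with an estimated correlation. Of these only 1 integrin-list member, lower, passed. The direction of the ribosomal list turned under quantile normalization (median -0.01). Without A76 array 1 the mitosis (camera adjusted p = 0.109), YAP/TAZ (0.0536), integrin (0.197) and ribosomal (0.132) lists lost their calls, as did the ribosomal list without DMSO array 1 (0.152) and the integrin list without DMSO array 2 (0.0942) or Scr array 2 (0.0516). Over all camera settings at the preset correlation, adjusted p ranged from 0.000888 to 0.527 for mitosis, 0.00143 to 0.237 for YAP/TAZ targets, 0.000212 to 0.197 for integrins and 0.000208 to 0.824 for ribosomal proteins.

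The other 22 lists tested with A76 had medians between -0.13 and 0.30 and camera adjusted p from 0.0929 to 0.973. Among them were fatty acid oxidation (median 0.14), fatty acid synthesis (0.03), cholesterol synthesis (0.08), oxidative phosphorylation (0.03), autophagy and lysosome (0.01), the interferon response (0.04) and DNA replication (0.08). Lists whose median, mean and test differed in sign were the subunits, fatty acid synthesis, autophagy, apoptosis regulators, extracellular matrix, epithelial mesenchymal transition, heat shock chaperones and keratinocyte markers. Markers of luminal cells, fibroblasts and blood cells had medians of -0.03, 0.30 and 0.09 with camera adjusted p of 0.511, 0.448 and 0.751, and the 3 keratinocyte markers tested had a median of 0.02. A76 array 2 had the highest median coefficient of variation between replicate spots, 6.93% against 2.60% to 3.63% on the others. With the array median as scale the counts were 75 higher and 183 lower, so 29.1% of called genes were higher in place of 40.5%. Without DMSO array 1 or 2 the counts were 12 and 13 or 8 and 12, without A76 array 1 or 2 they were 18 and 44 or 16 and 36, and without either Scr or either shRNA array 66 and 101 or 59 and 114, in fits with fewer residual degrees of freedom. Of 40 called genes followed across settings, most lost their call with some array left out. ATOH8, TGFB2, PCAT18, SERPIND1, EGR1, SLCO4A1, IL1B and PTGS2 were called under every setting that tested them. PCAT18, dim with DMSO, was not tested among genes well above background on all 8 arrays.

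In suspension cells carrying the shRNA, few transcripts passed the threshold, and no tested list had more than 2 members that did. MMP9, a gelatinase, fell by 2.11 ± 0.18 on the log2 scale, from 1.79 ± 0.07 with Scr to -0.31 ± 0.34 (SD, n = 2; limma adjusted p = 0.0148). NLRP3, the sensor of an inflammasome, fell 2.93-fold, and DDIT4L, an inhibitor of mTOR signalling, 3.45-fold. CADM1, a cell adhesion molecule, rose 4.74-fold, and the cancer-testis genes CSAG1 and SPANXA1 rose 3.78-fold and 2.45-fold, among 4 of 31 such genes that rose, a family picked after the values were seen. With normexp, whose offset shrinks changes of dim genes by construction, the log2 change of CSAG1 was 0.91 in place of 1.92 and that of SSX1, another of the 4, 0.45 in place of 3.30, while SPANXA1 stayed between 1.28 and 1.34 over the scalings. In all, 34 genes were higher and 62 lower at a limma adjusted p under 0.05, 0.429% of those tested, and 31 and 56 of them changed at least 2-fold.

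The other large rises with the shRNA were those of SLC14A1, a urea transporter (2.64-fold), WFDC2 (2.45-fold), the non-coding RNA UCA1 (2.24-fold), the tetraspanin TSPAN8 (2.08-fold) and the homeobox gene IRX5 (2.04-fold), with limma adjusted p for the 8 between 0.00956 and 0.0362. The other large falls were those of ZP1 (3.76-fold), PLA2G4D (3.75-fold), SLC37A1, a sugar phosphate transporter (3.44-fold), SLPI, a protease inhibitor (2.83-fold), and DEPP1 (2.62-fold), with limma adjusted p for the 8 between 0.00918 and 0.0312. Of the called genes 37 were not well above background in 1 of the groups. The cancer-testis gene SSX1, NUP210P1 and TCERG1L were read only with the shRNA and rose at least 3.34-fold, at least 2.48-fold and at least 1.76-fold. SORCS2, SMTNL1 and the matrix phosphoglycoprotein MEPE were read only with Scr and fell at least 6.37-fold, at least 4.87-fold and at least 4.52-fold.

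Hypoxia response genes had negative values with the shRNA in all 19 tested members, with a median log2 change of -0.38. CA9 fell 2.03-fold and was the only member past the threshold over all genes, while 8 were lower adjusted over the list alone. ANGPTL4 read -1.18, NDRG1 -1.15 and ADM -0.87 without passing. The list's camera adjusted p was 3.95e-10, but adjusted p = 0.253 with an estimated correlation. Of 21 glycolysis genes, ALDOC fell 2.09-fold and 6 were lower adjusted over the list alone. PFKFB4 read -0.77, the glucose transporter SLC2A1 -0.69 and ENO2 -0.52, and the median of -0.25 had a camera adjusted p of 4.39e-07, with adjusted p = 0.217 with an estimated correlation. Among 23 YAP/TAZ targets IGFBP3 fell 2.56-fold and the coagulation initiator F3 2.25-fold, with 6 lower adjusted over the list alone; CCN1 read -0.73 and AMOTL2 -0.40, and the camera adjusted p was 6.24e-06, with adjusted p = 0.211 with an estimated correlation.

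Other lists were shifted with the shRNA with few or no members past the threshold. None of 26 cytosolic ribosomal protein genes passed, RPS7 reading -0.26, RPL5 -0.24, RPS2 -0.23 and RPL18 -0.20; the median of -0.16 had a camera adjusted p of 1.99e-05, with adjusted p = 0.272 with an estimated correlation. This list lost its call under quantile normalization. None of 23 NF-kB and cytokine genes passed over all genes, but 6 were lower and 1 higher adjusted over the list alone. PTGS2 read -0.81, IL1B -0.77, IL1A -0.77 and IL11 -0.61, and the camera adjusted p was 0.000202, with adjusted p = 0.211 with an estimated correlation. Matrix proteases included 1 called member of 15, MMP9, and 5 lower adjusted over the list alone. MMP1 read -0.43, PLAU -0.42 and MMP10 -1.16, and the camera adjusted p was 0.00181, with adjusted p = 0.253 with an estimated correlation. Lists with positive medians were G2/M and mitosis (0.17, with KIF20A at 0.31 and TOP2A at 0.36), fatty acid synthesis (0.11, with MLXIPL at 0.99 and ACSS2 at 0.30) and p53 targets (0.04), none with a member past the threshold over all genes. Their camera adjusted p were 0.00181, 0.0042 and 0.0347, with adjusted p = 0.657, 0.253 and 0.405 with an estimated correlation. Without Scr array 2 the mitosis, protease and p53 lists lost their calls (camera adjusted p = 0.751, 0.0527 and 0.107), without shRNA array 2 the mitosis and fatty acid synthesis lists (0.633 and 0.0736), and without shRNA array 1 the p53 list (0.377). Over all camera settings at the preset correlation, adjusted p ranged from 2.42e-07 to 0.751 for mitosis, 4.31e-05 to 0.0527 for proteases, 6.04e-05 to 0.0736 for fatty acid synthesis, 0.00322 to 0.377 for p53 targets and 1.68e-10 to 0.792 for ribosomal proteins.

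The other 25 lists tested with the shRNA had medians between -0.17 and 0.15 and camera adjusted p from 0.172 to 0.979. The AMPK network list had a median of 0.05, fatty acid oxidation -0.06, cholesterol synthesis 0.01, autophagy and lysosome 0.02, and the ERK feedback genes -0.04. Markers of luminal cells, fibroblasts and blood cells had medians of 0.08, -0.13 and -0.07 with camera adjusted p of 0.448, 0.591 and 0.36, and the 3 keratinocyte markers a median of -0.05 and a mean of -0.33. Median, mean and test differed in sign for apoptosis regulators, SRF and actin cytoskeleton, stem and progenitor markers, the interferon response and NRF2 targets. With normexp background correction 83 genes were higher and 248 lower, so 25.1% of called genes were higher in place of 35.4%, and without a filter on dim probes 2 were higher and 9 lower. Without Scr array 1 or 2 the counts were 15 and 53 or 7 and 22, without shRNA array 1 or 2 they were 25 and 34 or 11 and 20, and without either DMSO or either A76 array 18 and 28 or 19 and 37. Of 29 called genes followed across settings, 27 lost their call with some array left out, and MEPE alone was called under every setting that tested it. MEPE, dim with the shRNA, was not tested among genes well above background on every array.

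Suspension changed far more transcripts: against attached DMSO cells, in suspension Scr cells many genes of DNA replication (23 of 26), mitosis (16 of 26) and the YAP/TAZ targets (14 of 23, with 3 higher) were lower. Many genes of the hypoxia response (13 of 19), the interferon response (15 of 24, with 2 lower) and the ER chaperones (10 of 18) were higher. As lists, these 6 passed by camera at the preset correlation but not with an estimated correlation, where adjusted p ranged from 0.253 to 0.632. ASB2, a specificity subunit of ubiquitin ligases, rose by 4.90 ± 0.14 on the log2 scale (29.9-fold), from 0.70 ± 0.16 with DMSO (SD, n = 2; limma adjusted p = 0.000127). The interferon-induced chemokine CXCL11 rose 25.4-fold, and MLXIPL, a glucose-responsive transcription factor of lipid synthesis, 23.6-fold. KRTAP2-3 fell 25.6-fold and CD274, which encodes the immune checkpoint ligand PD-L1, 6.32-fold. At a limma adjusted p under 0.05, 4042 genes were higher and 4718 lower, 39.1% of those tested, and 1688 and 1154 of them changed at least 2-fold.

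The other large rises in suspension were those of C9orf152 (26.1-fold), SPINK4 (23.2-fold), the NADPH oxidase NOX5 (22.9-fold), the chemerin receptor CMKLR1 (21.5-fold) and FCGBP (19.9-fold), with limma adjusted p for the 8 between 0.000127 and 0.00147. The other large falls were those of SORCS3 (10.2-fold), MARCHF4 (7.45-fold), the growth factor FGF5 (6.41-fold), the phosphodiesterase PDE1C (5.85-fold), the metalloprotease ADAMTS6 (5.81-fold) and the YAP target ANKRD1 (5.65-fold), with limma adjusted p for the 8 between 0.000127 and 0.000513. Read only in suspension, the chemokine CXCL10 rose at least 43.8-fold, RAB17 at least 15.0-fold and NCMAP at least 14.6-fold. Read only in attached cells, ESM1 fell at least 18.5-fold, MCIDAS at least 4.59-fold and CLCA3P at least 4.37-fold.

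Of 26 DNA replication genes, 23 fell in suspension and 3 did not pass. RRM2, a ribonucleotide reductase subunit, fell 4.06-fold, the clamp loader subunit RFC3 3.17-fold and the polymerase subunit POLE2 2.72-fold. Their median log2 change of -1.08 had a camera adjusted p of 4.71e-09, but adjusted p = 0.463 with an estimated correlation. In the G2/M and mitosis list 16 of 26 fell (19 adjusted over the list alone), CCNA2 2.26-fold, CDC20 2.12-fold, CENPA 2.04-fold and TTK 1.87-fold; the camera adjusted p was 6.68e-05, with adjusted p = 0.632 with an estimated correlation. Of 23 YAP/TAZ targets 14 fell and 3 rose, with CCN2 down 3.55-fold, GADD45A 3.39-fold and CCN1 2.59-fold; the camera adjusted p was 0.00127, with adjusted p = 0.253 with an estimated correlation. Metallothioneins, which bind metal ions and whose probes can cross-react between near-identical members, fell in 7 of 9, among them MT1M 4.01-fold and MT1E 2.47-fold; the camera adjusted p was 0.00109, with adjusted p = 0.463 with an estimated correlation.

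Hypoxia response genes rose in 13 of 19 members in suspension, none fell, and the median was 0.86. ANGPTL4 rose 7.16-fold, EGLN3 5.78-fold, ADM 3.66-fold and VEGFA 2.86-fold, and the camera adjusted p was 1.58e-06, with adjusted p = 0.277 with an estimated correlation. Of 24 interferon response genes 15 rose and 2 fell, with XAF1 up 4.97-fold, IFIT2 2.88-fold, IFIT3 2.45-fold and ISG20 2.42-fold; the camera adjusted p was 0.000349, with adjusted p = 0.272 with an estimated correlation. ER chaperones rose in 10 of 18, the co-chaperone DNAJB9 4.03-fold, HERPUD1 2.57-fold and the chaperone HSPA5 1.91-fold, and the camera adjusted p was 0.000202, with adjusted p = 0.272 with an estimated correlation. Of 20 FOXO targets 11 rose and 2 fell, with PDK4, an inhibitor of pyruvate oxidation, up 8.14-fold, the muscle ubiquitin ligase TRIM63 3.85-fold, CITED2 1.94-fold and catalase (CAT) 1.75-fold; the camera adjusted p was 0.000976, with adjusted p = 0.253 with an estimated correlation.

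Lower in the ranking in suspension, glycolysis genes rose in 8 of 21 and fell in 1, autophagy and lysosome genes rose in 12 of 24 and fell in 2, and TGF-beta targets rose in 11 of 20 and fell in 2. Oxidative phosphorylation genes fell in 9 of 25 with none higher, and cholesterol synthesis genes fell in 14 of 25 and rose in 3. Camera adjusted p for these 5 lists were 0.00374, 0.00437, 0.00799, 0.0174 and 0.0307, with adjusted p = 0.277, 0.333, 0.253, 0.463 and 0.277 with an estimated correlation. Luminal breast epithelial markers, which stood for another cell line, rose in 7 of 14 and fell in 1, with a median of 0.27, a camera adjusted p of 0.0191 and adjusted p = 0.272 with an estimated correlation; 4 of the 14, XBP1 among them, are also members of other lists. Fibroblast markers rose in 3 of 5 with a median of 1.31 (camera adjusted p = 0.0528), blood markers in 1 of 7 (0.23), and 2 of 3 keratinocyte markers fell. The oxidative phosphorylation list lost its call without DMSO array 1 (camera adjusted p = 0.0694) and under quantile normalization, and the cholesterol list without Scr array 2 (0.0761) and with the median or quantile scales. Their camera adjusted p at the preset correlation ranged from 0.000329 to 0.824 and from 0.000678 to 0.137.

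The other lists tested in suspension did not pass, with camera adjusted p up to 0.904. Cytosolic ribosomal proteins had a median of -0.14, heat shock chaperones -0.29, apoptosis regulators -0.27, matrix proteases 0.14, NF-kB and cytokines 0.13, and epithelial mesenchymal transition -0.17. Median, mean and test differed in sign for fatty acid synthesis, integrins, stem and progenitor markers, ERK feedback genes and NRF2 targets. The plot of list medians sets all 34 lists side by side. With the array median as scale, the median of all genes moved by -0.22, and the counts became 2647 higher and 7129 lower (27.1% higher in place of 46.1%), so changes here are relative to the 75th percentile. Attachment differs in this comparison together with the DMSO vehicle and the slide row, and without DMSO array 1 or 2 the counts were 2705 and 2792 or 2568 and 2723.

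**Figure D2:**
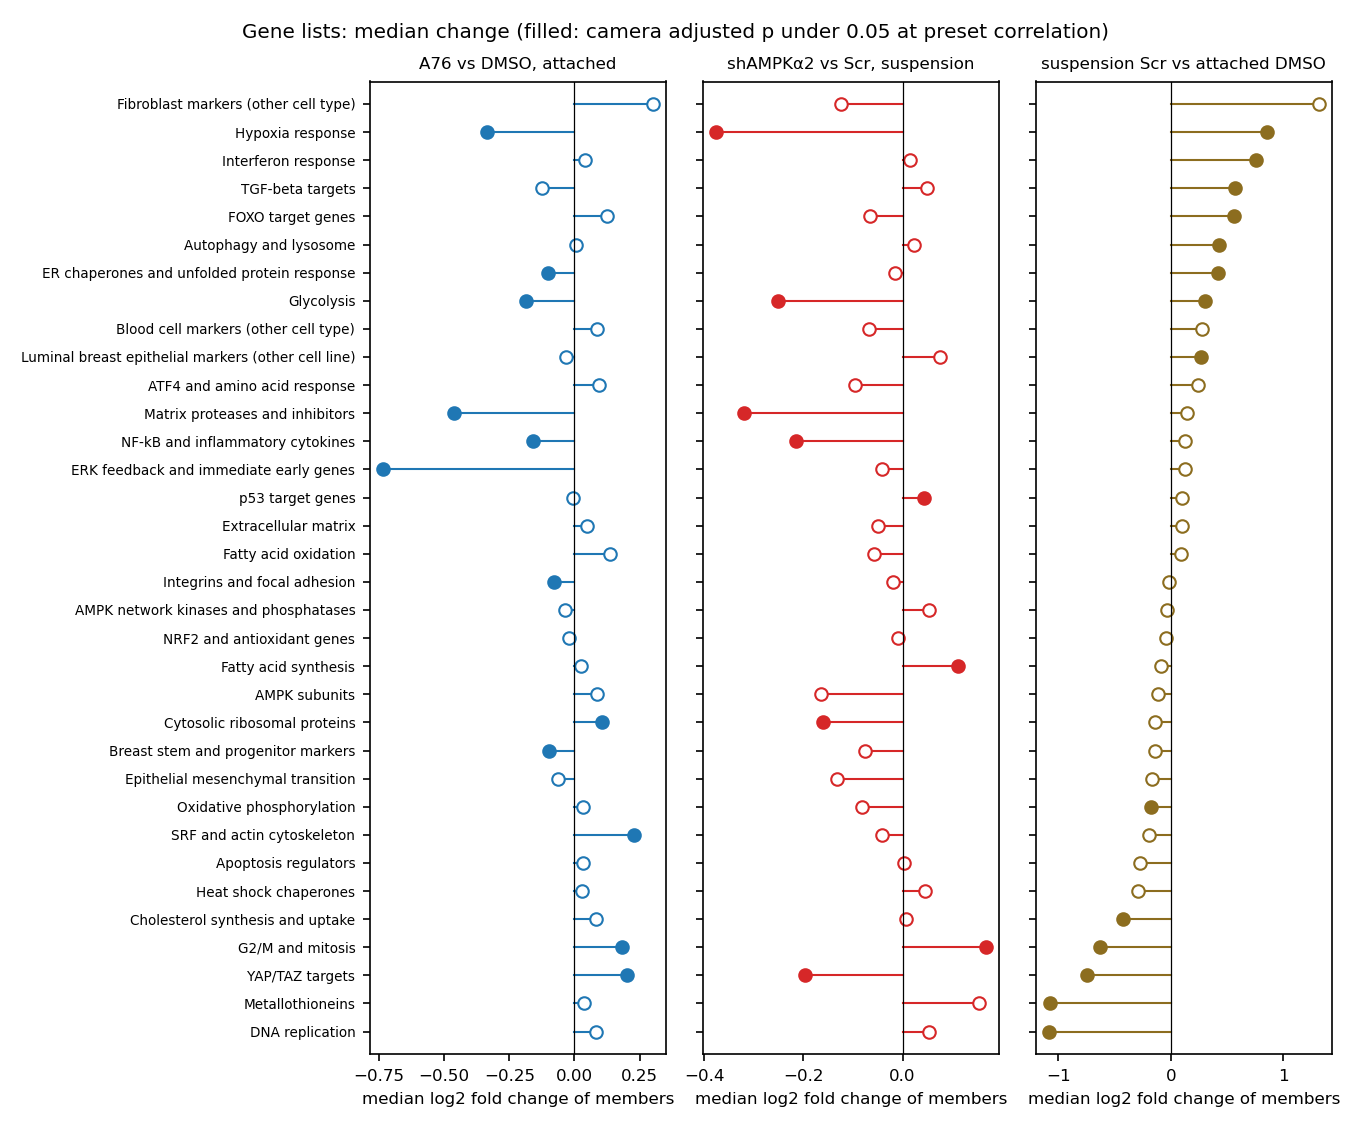
Median log2 fold change of the tested members (horizontal axis) of each of the 34 gene lists (vertical axis, ordered by suspension), with a panel for each of the 3 comparisons; filled points have a camera adjusted p under 0.05 at the preset correlation and open points do not. DNA replication lies at -1.08 and hypoxia response at 0.86 in suspension, while hypoxia response lies at -0.34 with A76 and -0.38 with the shRNA; with an estimated correlation 0 of the 35 filled points keep an adjusted p under 0.05.

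With an estimated correlation between genes, 0 of the 12, 9 and 14 lists called with A76, with the shRNA and in suspension kept a camera adjusted p under 0.05, while 5, 7 and 6 of the 34 lists had an unadjusted p under 0.05. By fry, 12, 9 and 26 lists passed, among them 9, 7 and 14 of those called by camera. Fry asks whether a list changed at all, while camera asks whether it changed more than other genes. With 39.1% of all tested genes called in suspension, a pass by fry there says little about camera's lists.

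The A76 and shRNA comparisons share no array, and their changes were nearly unrelated across 22386 genes (Pearson r = 0.02, Spearman rho = -0.02; genes are not independent replicates). Signs were alike for 47.8% of genes. Even so, 6 genes fell in both, against 0.479 for independent lists, and 0 fell with A76 and rose with the shRNA, against 0.263. Both comparisons took each gene's spread from the same fit, and the A76 and shRNA arrays shared slide columns. Calls are therefore not independent, and the values for independent lists, here and below, may be too low. CA9, which catalyses bicarbonate formation, fell 2.46-fold and 2.03-fold, NLRP3 2.57-fold and 2.93-fold, and PLA2G4D 4.69-fold and 3.75-fold. ZP1 fell at least 1.40-fold with A76, where it was not well above background, and 3.76-fold with the shRNA, and the unannotated transcript XLOC_l2_009139 fell 3.43-fold and 2.45-fold. RIMKLA, which makes a neuronal dipeptide, fell 1.53-fold and 2.46-fold. RIPOR3 rose 2.05-fold with A76 and fell 2.52-fold with the shRNA, the only gene called in opposite directions (0.327 for independent lists). XLOC_008552 was called higher in both, but was not well above background on any of the 4 suspension arrays.

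**Figure D3:**
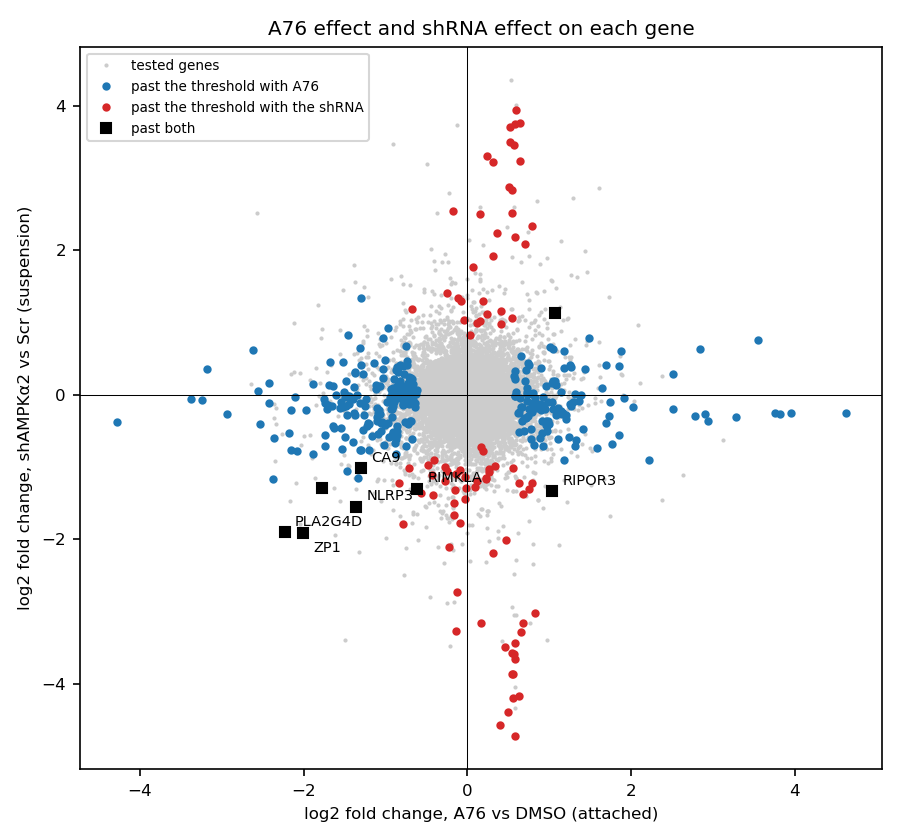
Log2 fold change with A76 in attached cells (horizontal axis) against log2 fold change with the shRNA in suspension cells (vertical axis) for each tested gene, with genes called in either comparison coloured and genes called in both as black squares. Points spread along both axes with r = 0.02, 6 of the black squares lie in the lower left, and dim genes read on no attached array form a cluster right of 0, their median A76 change being 0.44.

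Genes lower with the shRNA were often higher in suspension: 43 of the 62 were also called higher in suspension (11.2 for independent lists) and 9 lower (13.1). Of the 34 genes higher with the shRNA, 11 were called higher in suspension (6.14) and 8 lower (7.16). Both comparisons use the Scr arrays, which alone gives r = -0.50 across genes in simulation, and the observed r was -0.15. The covariance was -0.042 against a simulated -0.025. With the Scr arrays split between the comparisons, r was 0.05 and -0.06, so the sign of the relation depended on the array.

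Genes changed by A76 were also often higher in suspension. Of the 118 genes higher with A76, 65 were called higher in suspension (21.3 for independent lists) and 22 lower (24.9), and of the 173 lower, 82 were called higher (31.2) and 40 lower (36.5). SPINK4 rose both with A76 (3.68-fold) and in suspension (23.2-fold), while VEGFA fell 2.14-fold with A76 and rose 2.86-fold in suspension, and ANKRD1 and FILIP1L rose with A76 and fell in suspension. Across genes r was 0.19 and the covariance 0.053, against 0.50 and 0.025 simulated from the shared DMSO arrays alone. With the DMSO arrays split, r was 0.09 and 0.11 and the covariance 0.028 and 0.033.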

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

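The split-control percentages in the last paragraph were chosen after the results were seen; the other alternatives were set before the data were examined. Leaving out an array assumed that its group's lone array varied like the other groups, and cost a residual degree of freedom, which lowers counts by construction; for other settings the cause of a difference was not tested. Robust-trend camera tests of lists were not run, no block for slide or scan could be fitted with 1 of each, and PRKAA2 had a single probe. Comparing only 2 groups gives no value for relations between comparisons. Same-numbered arrays did not pair, with correlations of their deviations of 0.077 (DMSO with A76), 0.094 (DMSO with Scr), -0.005 (DMSO with shRNA), -0.001 (A76 with Scr), -0.109 (A76 with shRNA) and 0.093 (Scr with shRNA), so the replicate block is given here alone.

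Counts of genes higher and lower with A76, 118 and 173 as reported, were 75 higher with the median of each array, 370 and 423 with normexp and the 75th percentile, 261 and 317 with normexp and quantile normalization, 20 and 27 with no filter on dim probes, and 203 higher among genes well above background on all 8 arrays. They were 11 and 21 with only the 2 groups, 59 and 97 with the replicate block, 307 and 381 with an intensity trend (341 and 405 robust), 61 and 102 at an absolute log2 fold change of at least 1, and 271 and 312 at an adjusted p under 0.1. Leaving out 1 array gave 8 to 66 higher and 12 to 114 lower.

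With the shRNA, 34 and 62 as reported became 83 and 248 with normexp and the 75th percentile, 81 and 162 with normexp and quantile normalization, 2 and 9 with no filter, 3 and 10 with only the 2 groups, 20 and 31 with the block, 80 and 247 with a trend (84 and 261 robust), and 70 and 152 at an adjusted p under 0.1. With 1 array left out the range was 7 to 25 higher and 20 to 53 lower. In suspension, 4042 and 4718 became 2647 and 7129 with the median of each array and 1688 and 1154 at an absolute log2 fold change of at least 1, and with 1 array left out 2568 to 3948 and 2723 to 4551.

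Values that turned sign were mostly small, but 2 large ones were lost with normexp and the 75th percentile, both of genes near background: XLOC_008552 with the shRNA, called at 1.14, became -0.0357, and HES1 with A76, not called at -1.92, became 0.0205. The same setting turned PRKAA1 with A76 (-0.0254) and PRKAA2 in suspension (-0.00368). No value was past the threshold after turning. With normexp and quantile normalization they were RPL18 with the shRNA (0.00801), and PRKAB1 (0.00166) and PRKAG3 (0.0421) in suspension, and with quantile normalization PRKAB1 in suspension (0.00168). The mean of all probes turned PRKAA1 with A76 (-0.0414) and in suspension (-0.198), and the median of each array turned PRKAA1 (-0.0985) and PRKAA2 (-0.170) in suspension. The ribosomal list with A76 had a median of -0.0102 with quantile normalization, 0.00541 (its test turned) with normexp and the 75th percentile, and -0.0296 with normexp and quantile normalization.

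With 1 array left out, values that turned ranged, with A76, from -0.0115 (without DMSO array 2) to 0.187 for PRKAA1, -0.21 to 0.0495 (without A76 array 2) for PRKAA2, which was 0.000363 without DMSO array 1, and -0.000917 (without DMSO array 1) to 0.143 for PRKAB1. With the shRNA they ranged from -0.59 to 0.372 (without shRNA array 2) for PRKAG1, which was 0.292 without Scr array 2, and -0.430 to 0.0991 (without Scr array 2) for PRKAG3. In suspension they ranged from -0.0630 (without Scr array 1) to 0.172 for PRKAA2, which was -0.0264 without DMSO array 2, from -0.15 to 0.102 (without Scr array 1) for PRKAB1, which was 0.0488 without DMSO array 2, and from -0.38 to 0.151 (without Scr array 1) for PRKAG3.

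Across genes, the A76 and shRNA effects correlated at r = -0.10 with normexp and the 75th percentile, -0.0524 with no filter, and -0.0360 to 0.0624 with 1 array left out. The shRNA and suspension effects correlated at -0.0367 with normexp and the 75th percentile, -0.00573 with normexp and quantile normalization, -0.314 with no filter, -0.0393 with genes above background on all 8 arrays, and -0.319 to -0.12 with 1 array left out. The A76 and suspension effects correlated at 0.236, 0.103 and 0.388 with the first 3 of these, and 0.17 to 0.276 with 1 array left out. With an estimated inter-gene correlation 0 of 35 list shifts passed. With Scr arrays split, 9 of 15 and 7 of 7 genes higher and 39 of 53 and 19 of 22 genes lower with the shRNA were higher in suspension, and with DMSO arrays split 10 of 12 and 5 of 8 genes higher and 8 of 13 and 9 of 12 genes lower with A76.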

Other observations

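The tests of hypoxia and glycolysis genes and of cell-type markers, and the families in the next 2 paragraphs, were chosen after the results were seen.

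In suspension, many histone, mitochondrial ribosomal protein, tubulin, CCT chaperonin and proteasome genes were lower than in attached cells. Of 67 histone genes 40 fell and none rose (median log2 change -0.55, from -0.77 to -0.40 over the other scalings), of 77 mitochondrial ribosomal proteins 52 fell (median -0.47, -0.70 to -0.25), of 16 tubulins 12 fell (median -0.69, -0.91 to -0.53, with TUBB2A at -1.46), and of 8 subunits of the CCT chaperonin 7 fell (median -0.63, -0.85 to -0.44). Among other chaperones, ER chaperones rose in 10 of 18, while heat shock chaperones went both ways but leaned lower (3 higher, 8 lower of 18, median -0.29). Proteasome subunits fell in 23 of 37 (median -0.41, -0.64 to -0.20) and rose in 3, among them the interferon-induced subunits PSMB9 and PSMB10 (0.99 and 1.11). HLA genes, which present antigens, rose in 16 of 20 with none lower (median 1.05, 0.83 to 1.20), including HLA-DMA (1.75) and HLA-DMB (1.85).

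Many protocadherin, plexin, S100 and clock genes were higher in suspension. Protocadherins rose in 20 of 31 and fell in 1 (median 0.74, 0.34 to 0.61 over the other scalings), plexins in 6 of 8 (median 0.98, 0.62 to 1.03, PLXNA1 at 1.88), and calcium-binding S100 genes in 8 of 14 (median 0.64, 0.34 to 0.50, S100P 13.2-fold). Circadian clock genes rose in 8 of 12 and fell in 1 (median 0.94, 0.69 to 0.91). BHLHE41 read 1.94 (1.71 to 2.02 over the other scalings) and BHLHE40 1.79 (1.57 to 1.86). TEF at 1.46 (0.72 to 1.37) and DBP at 1.12 (0.67 to 1.05) depended more on the scaling or background handling. With A76, 3 of 8 EGF-family ligands fell (EREG -1.48, AREG -1.38, NRG2 -0.81; median -0.34, -0.40 to -0.05). Of 31 cancer-testis genes 4 rose and none fell with the shRNA (median 0.15, 0.01 to 0.19).

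Hypoxia and glycolysis lists had negative medians with A76 and with the shRNA, with 3 of 19 and 0 of 21 members past the threshold with A76 and 1 of 19 and 1 of 21 with the shRNA. The shifts passed by camera at the preset correlation, but with an estimated correlation the adjusted p was 0.277 and 0.253 with A76 and 0.253 and 0.217 with the shRNA. At the preset correlation the tables argue against a single array as the source, since with each of the 4 arrays of a comparison left out the largest camera adjusted p of either list was 0.00679 and the weakest median -0.14. The largest camera adjusted p over 5 scaling and background settings was 0.000291, with the array median. That setting and the deposited value table shift each array by 1 constant, which camera's comparison with other genes largely cancels, so they decide little. Under quantile normalization and both normexp settings the largest camera adjusted p was 0.000160. These settings argue against array scaling or background handling as the whole source. Even so, normexp and quantile normalization took the glycolysis median with the shRNA from -0.25 to -0.14 and the hypoxia median with A76 from -0.34 to -0.23. The A76 and shRNA arrays lay in the same slide columns, apart from those of DMSO and Scr. Neither test can remove an effect of slide column, which stays open. Oxygen and cell density in culture are not given and stay open, and no biological explanation was tested.

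Genes lower with the shRNA were mostly higher in suspension, as 52 of 62 (83.9%) had a positive suspension value, against 46.9% of all genes. With calls made with 1 Scr array and the suspension value from the other, 73.6% and 86.4% were higher in suspension, against 44.6% and 49.4% of all genes. This split cannot exclude chance values of the shared Scr arrays, since the filter on dim probes used both. Of the 62 genes, 19 were not well above background with the shRNA, so some may have been tested only because both Scr arrays read high. The pattern was not particular to these genes, since 25 of 34 genes higher with the shRNA (73.5%) and 78 of 118 higher (66.1%) and 103 of 173 lower (59.5%) with A76 were also higher in suspension. The genes are not independent, and the shares of all genes were not matched for signal. Tested genes read on none of the 4 arrays of the suspension comparison had a median log2 change of 0.66 in it. With no filter on dim probes, the median suspension change of all genes was 0.15 in place of -0.04. Of the 96 genes called with the shRNA, 37 were not well above background in 1 group. Why called genes of every kind tend to be higher in suspension stays open, and a share of dim probes in this was not tested.

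In the shRNA comparison 183 genes were read on both arrays of 1 group and neither of the other and lay at least 2-fold apart, 101 with the shRNA and 82 with Scr. The crossed splits of the 4 arrays gave 33 and 19 such genes, a ratio of 5.55 to the larger. Chance values of dim probes stay open, since a crossed split could count only genes that passed the filter through a group outside the comparison. With A76 the pattern was alike: 126 such genes, 25 with A76 and 101 with DMSO, against 18 and 16 in the crossed splits. It was thus not particular to the shRNA comparison. Keratinocytes or fibroblasts in 1 group, as a share large enough to bring most of their markers, are argued against: of markers not read in 1 group, 0% (0 of 11 and 0 of 7) were read on both arrays of the other, with exact 95% upper limits of 28.5% and 41.0% against a bound of 50% set after the result was seen. All these limits treat markers as independent, which markers of 1 cell type are not. Luminal and blood cells stay open, since 14 of 16 and 7 of 10 of their markers were read in both groups and only 2 and 3 could be used (0% of each, upper limits 84.2% and 70.8%), as does a small share of any type. The cells with Scr and with the shRNA carry different constructs, and differences that arose between them in culture stay open beside the shRNA itself, untested.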
